A study of Mus musculus with 8 samples.

How the data were processed

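RNA was taken from individual livers of 4 wild-type and 4 glycerol kinase knockout mouse pups, and each was hybridised to 1 Affymetrix Mouse 430 2.0 array. Per the labels, the deposited values are signal intensity from Affymetrix GCOS 1.2 at default settings, scaled on every array to a target of 500 over all probe sets. They were checked to be linear, with 45101 probe sets per array and a mean of 500.0 after trimming 2% from each end, and that scaling was kept. The table holds no detection calls. Groups were taken from the sample titles.

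Probe sets were named from the platform's annotation joined by Entrez identifier to a RefSeq gene table, which gave 34945 probe sets 1 gene, 932 several and 9160 none, after 64 control probe sets were left out. For 204 named probe sets the identifier was not in the gene table. No probe set was paired with the glycerol kinase gene, so its planned comparison was not analysed here. No gene was guessed for a probe set without a name.

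The 20395 probe sets with a signal of at least 200 on at least 4 of the 8 arrays were tested, which named 10878 genes. Log2(signal + 16) was compared between the groups with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), and probe sets with a Benjamini-Hochberg adjusted p under 0.05 were called. Fold changes are knockout minus wild type on the log2 scale, with limma's standard error. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

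The text names the 12 genes with the largest rise and the 12 with the largest fall among called probe sets that stand for exactly 1 gene and whose groups do not overlap, with the brightest such probe set per gene. In each list it names up to 4 members past the threshold by smallest p, and where fewer than 2 passed, members by smallest p up to 2. A gene is represented in lists by its brightest tested probe set. Sf3b1 was the 1 called gene with probe sets of both signs (-1.09 and 0.17).

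Lists of genes for 26 pathways and of markers for 14 cell types or tissues were fixed, with the tests and the rule for naming genes, before the data were examined. They were tested with limma's camera at a preset inter-gene correlation of 0.01, and also with the correlation estimated per list and with fry, which asks whether a list's genes move on balance 1 way. Adjustment was over the gene lists and over the cell type lists separately. The skeletal muscle list had fewer than 2 measured members and was not tested.

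The comparison was tested on simulated data with 200 probe sets changed at each of 3 sizes. It recovered 23.5% of changes of 1.5-fold, 58.0% of 2-fold and 93.5% of 4-fold. Of 376 calls, 26 (6.91%) were of unchanged probe sets, and 0 were made with no change. Noise was drawn independently for each probe set, without the correlation between the real ones. The share of false calls in the real data can therefore differ. The real data gave 61 calls and so a stricter cutoff, under which smaller shares would be recovered. With independent genes, camera called both lists shifted by 0.3, and it called 0 lists in data with no shift. With the correlation of the real data and no group effect, the preset correlation called a median of 7 lists and at most 17 over 50 data sets. The arrays of these data sets were drawn with replacement from the residuals of the real arrays, with random signs. Copies of an array can therefore recur in a data set, and the hybridisation sets were not kept balanced over the groups. The counts are thus not the rate for independent, balanced arrays.

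The alternatives were other pseudocounts, signal minimums, scalings, thresholds, limma settings and probe set choices, the replicate number as a block, and each array left out. The hybridisation set, read from control probe sets since the labels give no batch, was used as a block, with and without the array labelled wild type 4, and each set was analysed alone; these were added after the data were examined.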

Results

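Liver RNA was measured in mouse pups lacking glycerol kinase and in wild-type littermates of the same age, all given by the labels as male and as sampled on day of life 3. Glycerol kinase, encoded by Gk on chromosome X (older symbol Gyk), phosphorylates glycerol to glycerol 3-phosphate. The design of the series states that day 3 was taken because the pups show symptoms then, hypoglycemia and acidosis among them. Each of 4 wild-type and 4 knockout livers of the C57BL/6J strain was hybridised to its own Affymetrix Mouse 430 2.0 array, which reads transcripts with probe sets, groups of short probes for 1 transcript region. The deposited values are signal intensities on a linear scale. The mean signal after trimming 2% from each end was 500.0 on every array, and the median ran from 147 to 175. Of the probe sets, 42.6% to 46.7% reached a signal of 200 on an array. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.19.

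The arrays differed in ways that the groups did not explain. The array labelled wild type 4 carried a female signal: Xist, the RNA that coats the inactive X chromosome, stood at 10506 there and between 196 and 396 on the other 7 arrays, and the Y-linked Eif2s3y at 1.3 against 685 to 1164. Control probe sets parted replicates 1 and 2 of both groups from replicates 3 and 4. The spiked-in BioB control lay between 141 and 167 on the first set and between 258 and 338 on the second, and the 3'/5' ratio of the transferrin receptor, a transcript of the mouse itself, between 6.50 and 6.72 against 4.21 to 4.83. These are called the first and the second hybridisation set here, although the transferrin receptor ratio reads the sample RNA or its labelling and not the hybridisation. Knockout 1 and 2 had the highest 3'/5' ratios of the pyruvate carboxylase control, a sign of RNA quality, at 7.03 and 4.93 against 2.06 to 3.46 on the other 6 arrays. The other ratios did not set knockout 2 apart: for actin it stood at 1.27, below wild type 1 (1.32), with knockout 1 at 1.74, and for Gapdh knockout 1, knockout 2 and wild type 1 stood at 0.896, 0.886 and 0.886. On the first principal component, which held 39.9% of the variance, knockout 1 lay at 69.8 and knockout 2 at 31.4, and the other 6 arrays between -34.9 and -2.23.

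**Figure D1:**
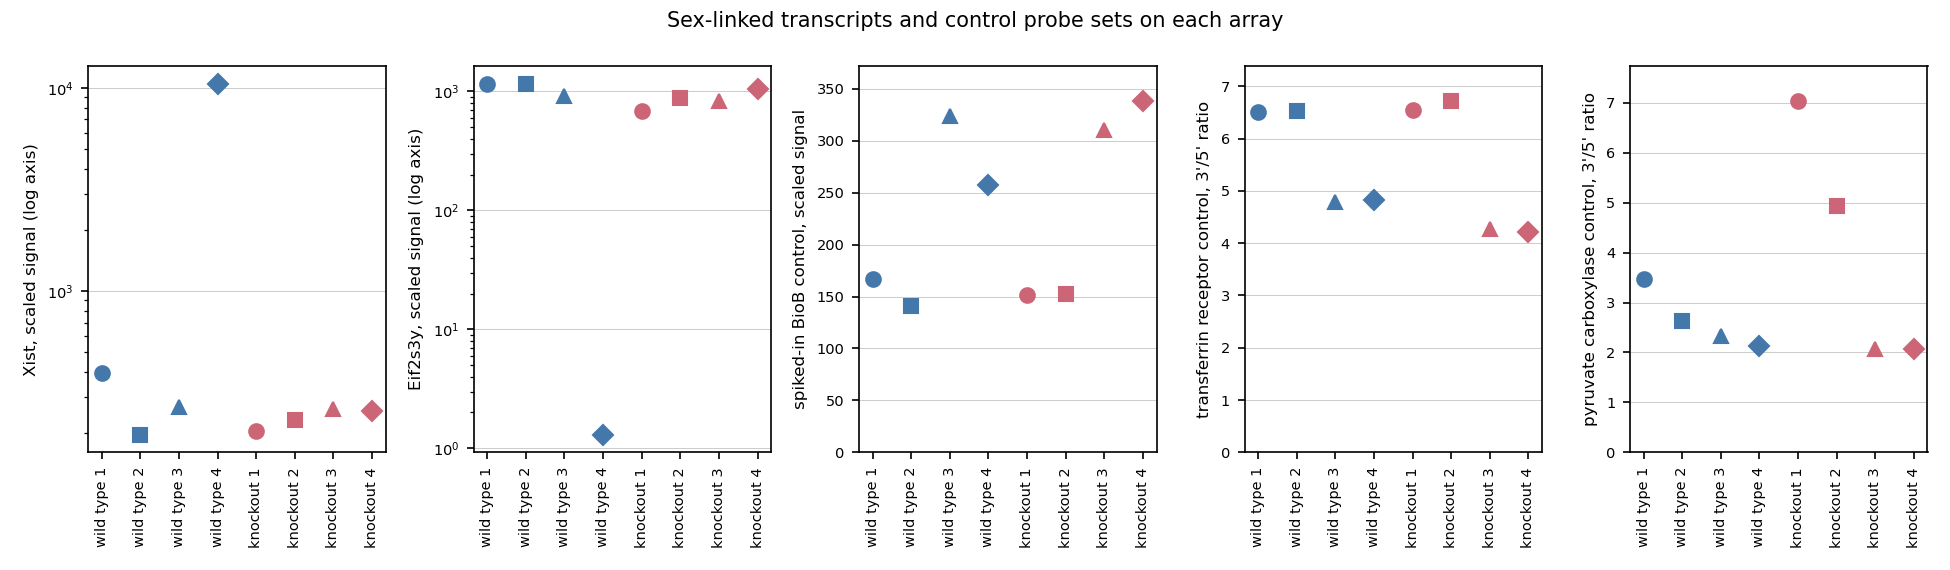
Signals of Xist and Eif2s3y (log axes), the signal of the spiked-in BioB control and the 3'/5' ratios of the transferrin receptor and pyruvate carboxylase controls (linear axes from 0), 1 point per array. The array labelled wild type 4 stands alone with an Xist signal of 10506 and an Eif2s3y signal of 1.3, and the BioB control parts replicates 1 and 2 (141 to 167) from replicates 3 and 4 (258 to 338).

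The main comparison asks which liver transcripts differ in level when glycerol kinase is missing. The targeted gene itself was not analysed here, because the annotation used pairs no probe set with it, so its level did not check the group labels. The 2 probe sets with the smallest p have no gene name in that annotation. Their signals were 4281 ± 630 and 2769 ± 188 in wild type and 287 ± 66.1 and 174 ± 51.7 in the knockout (mean ± SD, n = 4 each), log2 fold changes of -3.84 ± 0.18 and -3.92 ± 0.20 (SE; limma adjusted p = 9.35e-06 and 1.05e-05).

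Among named genes past the threshold, the largest rises in the knockout were those of Acot1 and Ddit4. The largest falls were those of Car3, which encodes a carbonic anhydrase, Cyp1a2 and Gpd2. Acot1, which cleaves fatty acyl-CoA in the cytosol, had a signal of 766 ± 244 in wild type and 3297 ± 1589 in the knockout, 4.31 times as high (SD, n = 4; log2 fold change 2.02 ± 0.33 SE; limma adjusted p = 0.0466). Ddit4, an inhibitor of the growth kinase mTOR complex, was 4.40 times as high (389 ± 83.3 against 1713 ± 808; log2 fold change 1.96 ± 0.34). Psat1, of serine synthesis, rose by 1.44 ± 0.23 on the log2 scale, and Slc38a2, a neutral amino acid transporter, by 1.30 ± 0.18 (limma adjusted p = 0.0252). The other large rises were those of the matrix protein gene Npnt (1.43), the retinol saturase Retsat (1.33), the imprinted gene Peg3 (1.25), the lysosomal Tmem106b (1.23), the monoacylglycerol lipase Abhd6 (1.17), Smcp (1.13), Tedc2 (1.12) and the syndecan gene Sdc2 (1.11). In each of these 12 rises knockout 1 had the highest and knockout 4 the lowest knockout signal. For Acot1 they were 5385 and 1884, and for Ddit4 2640 and 696, beside 511 on wild type 4. Some of these genes rest on 1 of several probe sets: 1 of 4 was called for Npnt, with the lowest at 0.32, 1 of 3 for Sdc2 (0.23), 1 of 2 for Abhd6 (0.42) and 1 of 2 for Slc38a2 (0.68).

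The largest fall among named genes past the threshold was that of Car3, from 4543 ± 2440 to 387 ± 323 (SD, n = 4; log2 fold change -3.61 ± 0.57 SE; limma adjusted p = 0.0441). Cyp1a2, a drug-metabolising cytochrome P450, went from 3181 ± 1275 to 699 ± 174 (-2.11 ± 0.27; adjusted p = 0.0225). Gpd2, the mitochondrial glycerol 3-phosphate dehydrogenase, fell from 1806 ± 740 to 497 ± 127 (-1.77 ± 0.31; adjusted p = 0.0488). Hsd17b2, which oxidises sex steroids, changed by -1.73 ± 0.23, and Inhbe, a hepatic activin subunit, by -1.54 ± 0.22. Smoc2 (-1.36), the dicarboxylate transporter Slc13a3 (-1.26), Arrdc3 (-1.24), the immunoproteasome subunit Psmb10 (-1.23), the guanylate-binding protein Gbp7 (-1.21), the glutathione synthesis subunit Gclm (-1.20) and cyclin D1 (Ccnd1, -1.13) followed. The other probe set of Gclm stood at -0.12, and the weakest of 3 for Slc13a3 at -0.56. By the rule that chose these 24 genes, the 4 knockout arrays of each lay on 1 side of the 4 wild-type arrays. Acot1 and Acot2 are near-identical paralogs, so their values are uncertain where probes bind both.

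**Figure D2:**
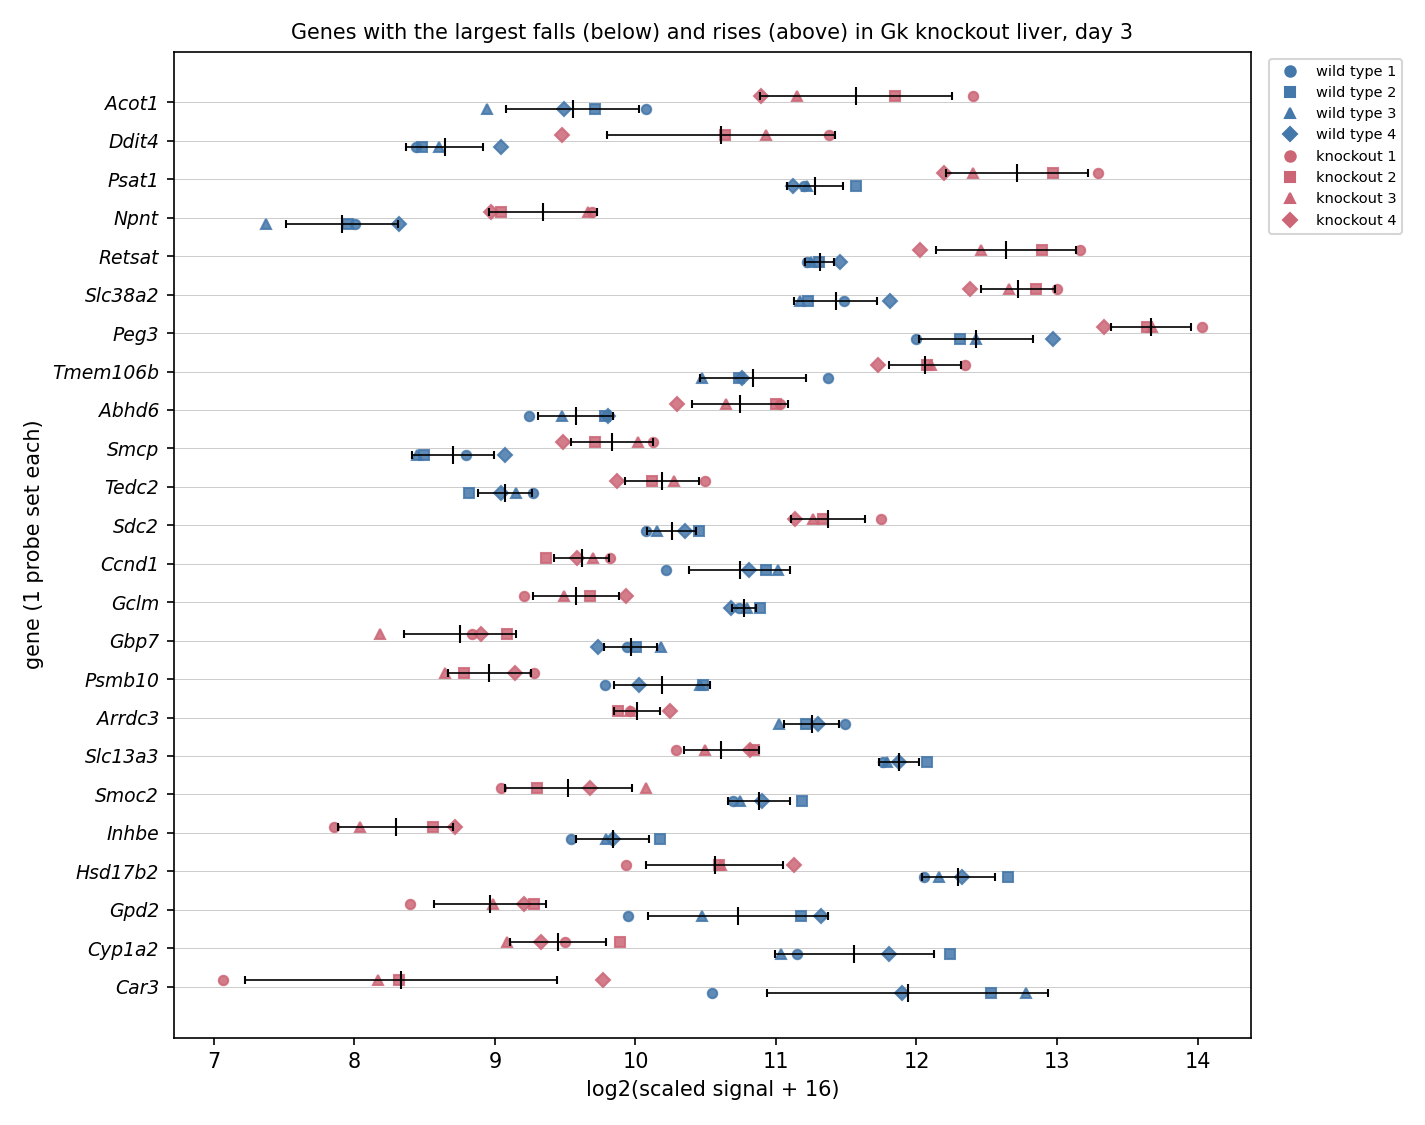
Log2(scaled signal + 16) on each array for the 12 genes with the largest rises and the 12 with the largest falls past the threshold; points are arrays, black bars the group mean and SD (n = 4). By the rule for naming genes, the knockout points lie wholly above the wild-type points for the rises, led by Acot1 (log2 fold change 2.02), and wholly below for the falls, led by Car3 (-3.61).

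In all, 30 of the 20395 probe sets tested were higher and 31 lower in the knockout (limma, Benjamini-Hochberg adjusted p under 0.05), which stand for 22 and 24 named genes. At an unadjusted p under 0.05 there were 1453 higher and 1493 lower probe sets, against 1020 expected in all with no difference. Correlation between probe sets widens the spread around that number. Of the 34 other splits of the arrays into 4 and 4, 2 gave more than the 2946 found between knockout and wild type. These were 3507 for the split by hybridisation set and 2988 for wild type 1 with knockout 1 to 3. The groups did not overlap for any of the 61 called probe sets, and for 1901 of those tested (9.32%, against 2.86% by chance). With the hybridisation set as a block, 103 probe sets were higher and 81 lower, the 61 among them. Within the first set alone 24 were higher and 6 lower, and within the second 0 and 2, the 2 being the unnamed probe sets above; at an unadjusted p under 0.05 these sets gave 3218 and 2931. All 61 had the same sign in both sets, which was fixed in advance because their groups do not overlap. A test of the difference between the sets called 2 probe sets, for Gins2 and Pvr, which were named after their values were seen, and at an unadjusted p under 0.05 it gave 2023 (9.92%), 6 of the 61 among them. Without the array labelled wild type 4 there were 4 higher and 2 lower, and with the hybridisation set as a block as well, 103 and 51. The number of calls also hung on other single arrays: there were 2, the unnamed probe sets, without wild type 2, wild type 3, knockout 2 or knockout 3, 22 without knockout 1 and 334 without knockout 4.

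Genes were also compared in 26 lists fixed before the data were examined. Camera, which tests whether a list's genes differ more than the other genes, called 12 lists with its preset correlation between genes of 0.01, 11 higher and 1 lower in the knockout. With the correlation estimated from the data camera called 0 of the 26, and the rotation test fry called 0 as well. At an unadjusted p under 0.05 there were 13 lists with the preset correlation, 1 with an estimated one and 7 by fry. Simulated data were made from the residuals of the real arrays, with no group effect. There the preset correlation called at least 1 list in 49 of 50 data sets and 12 or more in 10, and the estimated one called lists in 0. Arrays were drawn with replacement and random signs, so copies can recur and the hybridisation sets were not kept balanced. These counts are therefore not the rate of false calls for independent, balanced arrays. Of the 4 knockout arrays, knockout 1 lay farthest from wild type for each of the 12 called lists. Below, "called" refers to the preset correlation, and each adjusted p with an estimated correlation is given beside it. Members that did not pass over all probe sets tested are given as values, with adjusted p between 0.0515 and 0.957.

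Genes of glycerol and glycerol 3-phosphate handling went both ways. Of 15 measured, 1 fell (Gpd2) and 0 rose over all genes tested; adjusted over the list alone, 4 rose and 3 fell. The other glycerol 3-phosphate dehydrogenases on the list, Gpd1 and Gpd1l, chosen after their values were seen, stood at -0.15 and 0.50. Aqp8, an aquaporin, had a log2 fold change of -1.76 ± 0.32. The other aquaporins measured on the list did not fall: Aqp3 stood at 0.69, a rise adjusted over the list alone, and Aqp9 at 0.09. They were chosen after their values were seen, and Aqp7 was not measured. The list's median was 0.08 and its mean -0.12, camera leaned higher, and it was not called (adjusted p = 0.758 by camera and 0.880 with an estimated correlation).

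Gluconeogenesis genes were called higher, with a median of 0.34 and 16 of 18 above 0 (camera adjusted p = 1.14e-05; adjusted p = 0.369 with an estimated correlation). No member passed over all genes tested, and 6 rose and 0 fell adjusted over the list alone. The tyrosine aminotransferase Tat had a value of 1.33 ± 0.26 and the malate dehydrogenase Mdh1 of 0.45 ± 0.11. Pck1 (0.61), Got1 (1.07), Lpin1 (1.64) and Ppargc1a (1.42) also rose adjusted over the list alone. The enzymes Pck2, G6pc, Fbp1 and Pcx stood near 0, at 0.08, 0.06, -0.05 and -0.05. These genes were chosen after their values were seen. Hepatocyte markers, of which Hnf4a is also on this list, lay above 0 as well (11 of 11), with medians of 0.32 in the first hybridisation set and -0.11 in the second beside 0.59 and 0.14 for gluconeogenesis. In the urea cycle and amino acid catabolism list Tat had the smallest p, followed by the cystathionine lyase Cth (1.02 ± 0.22). The tryptophan dioxygenase Tdo2 had the largest value of this list (2.78 ± 0.65), and that of Got1 (1.07 ± 0.36) also exceeded Cth; both were chosen after their values were seen and rose adjusted over the list alone. That list had a median of 0.40 with 31 of 36 above 0, and 0 passed over all genes (12 rose and 1 fell adjusted over the list alone; camera adjusted p = 1.45e-09; adjusted p = 0.369 with an estimated correlation). Its medians on knockout 1 to 4 were 0.86, 0.34, 0.43 and 0.02. Glucocorticoid and fasting targets had the largest median, 0.56, with 17 of 21 above 0 and Ddit4 the 1 member that rose (5 rose and 1 fell adjusted over the list alone; camera adjusted p = 3.09e-06; adjusted p = 0.369 with an estimated correlation). On knockout 4 the median of this list was -0.05 and on knockout 1 it was 0.85.

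Fatty acid oxidation genes and targets of the nuclear receptor PPAR alpha were called higher, with a median of 0.21 and 30 of 39 above 0 (camera adjusted p = 3.00e-06; adjusted p = 0.369 with an estimated correlation). The 2 members that rose, Acot1 and the mitochondrial Acot2 (0.99 ± 0.15; limma adjusted p = 0.0331), cleave acyl-CoA rather than oxidise it. Adjusted over the list alone 8 rose and 0 fell, among them the oxidation enzymes Ehhadh (1.15), Eci2 (1.03), Acadm (0.40) and Acadl (0.39), and the thioesterases Acot3, Acot4, Acot8 and Acot12 stood at -0.06, -0.23, -0.29 and -0.05; these were chosen after their values were seen. Hepatocyte markers had medians of 0.32 and -0.11 in the sets, beside 0.34 and 0.08 for this list. Of the respiratory chain genes, 50 of 51 lay above 0, at a median of 0.26 (camera adjusted p = 4.49e-12; adjusted p = 0.369 with an estimated correlation). None passed over all genes tested and 5 rose adjusted over the list alone. Uqcrfs1 of complex III had a value of 0.49 ± 0.10 and Atp5c1 of the ATP synthase 0.52 ± 0.12. The citric acid cycle and pyruvate dehydrogenase list had a median of 0.20 and 22 of 28 above 0, with 0 passing over all genes and 7 rises and 1 fall adjusted over the list alone (camera adjusted p = 0.000114; adjusted p = 0.369 with an estimated correlation). Its isocitrate dehydrogenase subunit Idh3a stood at 0.60 ± 0.13 and the pyruvate carrier Mpc1 at -0.46 ± 0.10. Of the 4 probe sets tested for Idh3a only 2 lay above 0, and the lowest stood at -0.42.

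Amino acid response genes, targets of the transcription factor ATF4, held 3 of the genes that rose, Slc38a2, Psat1 and Ddit4, and 0 that fell, both over all genes and adjusted over the list alone. Their median was 0.19 with 20 of 26 above 0 (camera adjusted p = 0.00187; adjusted p = 0.369 with an estimated correlation). This list's medians within the 2 hybridisation sets were alike, 0.18 and 0.22. Hypoxia inducible genes were called higher at a median of 0.19, with 14 of 18 above 0, 0 passing over all genes and 1 rise adjusted over the list alone (camera adjusted p = 0.00684; adjusted p = 0.369 with an estimated correlation). Of these, P4ha2 had a value of 0.83 ± 0.20 and Bnip3 of 0.97 ± 0.29.

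Cell division genes were the 1 list called lower. All 31 measured lay below 0, at a median of -0.47 (camera adjusted p = 3.90e-07; adjusted p = 0.532 with an estimated correlation). Cyclin D1 was the 1 member that fell, over all genes and adjusted over the list alone, and the ribonucleotide reductase Rrm2 had a value of -0.78 ± 0.29. The list's medians on knockout 1 to 4 were -1.12, -0.52, -0.21 and 0.07, and on the wild-type arrays they ran from -0.22 to 0.26. With a 3'/5' ratio as a covariate the median was -0.29 for pyruvate carboxylase, -0.29 for actin and -0.48 for Gapdh. Erythroid markers, of the blood-forming cells that newborn liver holds, had medians of -0.51 in the first hybridisation set and 0.17 in the second, beside -0.87 and -0.06 for cell division.

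The other 3 lists called higher had small medians, and their calls were lost in 8 (cytochrome P450), 7 (acute phase) and 10 (antioxidant) of the 24 other settings tried with the preset correlation, quantile normalization among them. Cytochrome P450 and xenobiotic genes (median 0.16, 19 of 26 above 0) held 1 rise, Cyp2f2 (0.72 ± 0.12; limma adjusted p = 0.0473), and 1 fall, Cyp1a2, with 4 and 2 adjusted over the list alone (camera adjusted p = 0.0260; adjusted p = 0.406 with an estimated correlation). Acute phase genes (median 0.09, 15 of 20 above 0) had 0 members passing over all genes and 2 rises adjusted over the list alone, with Crp at 0.65 ± 0.17 and Steap4 at 0.88 ± 0.25 (camera adjusted p = 0.0260; adjusted p = 0.646 with an estimated correlation). Antioxidant genes and NRF2 targets (median 0.08, 17 of 23 above 0) had 0 by either count, with Gstm1 at 0.78 ± 0.29 and Sod2 at 0.40 ± 0.15 (camera adjusted p = 0.0344; adjusted p = 0.551 with an estimated correlation). Gclm, a target of NRF2, is on this list through its brighter probe set, at -0.12, and the probe set that fell is not counted there.

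Since each hybridisation set holds 2 arrays of each group, the block left the medians of the lists as they were, and the same number of lists, 12, was called with it. Within the sets the medians were 0.59 and 0.14 for gluconeogenesis, 0.68 and 0.14 for amino acid catabolism, 0.92 and 0.21 for glucocorticoid targets, 0.34 and 0.08 for fatty acid oxidation, 0.39 and 0.13 for the respiratory chain and 0.34 and 0.15 for the citric acid cycle. They were 0.18 and 0.17 for hypoxia inducible genes, 0.30 and 0.08 for cytochrome P450 genes, 0.32 and -0.12 for acute phase genes and 0.25 and 0.01 for antioxidant genes. Hepatocyte markers had medians of 0.32 and -0.11, close to those of the acute phase genes. Camera called 14 lists in the first set, hypoxia inducible genes not among them. It called 6 in the second: amino acid catabolism, ATF4 targets, the respiratory chain, the citric acid cycle, hypoxia inducible genes and, lower, lipoproteins.

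**Figure D3:**
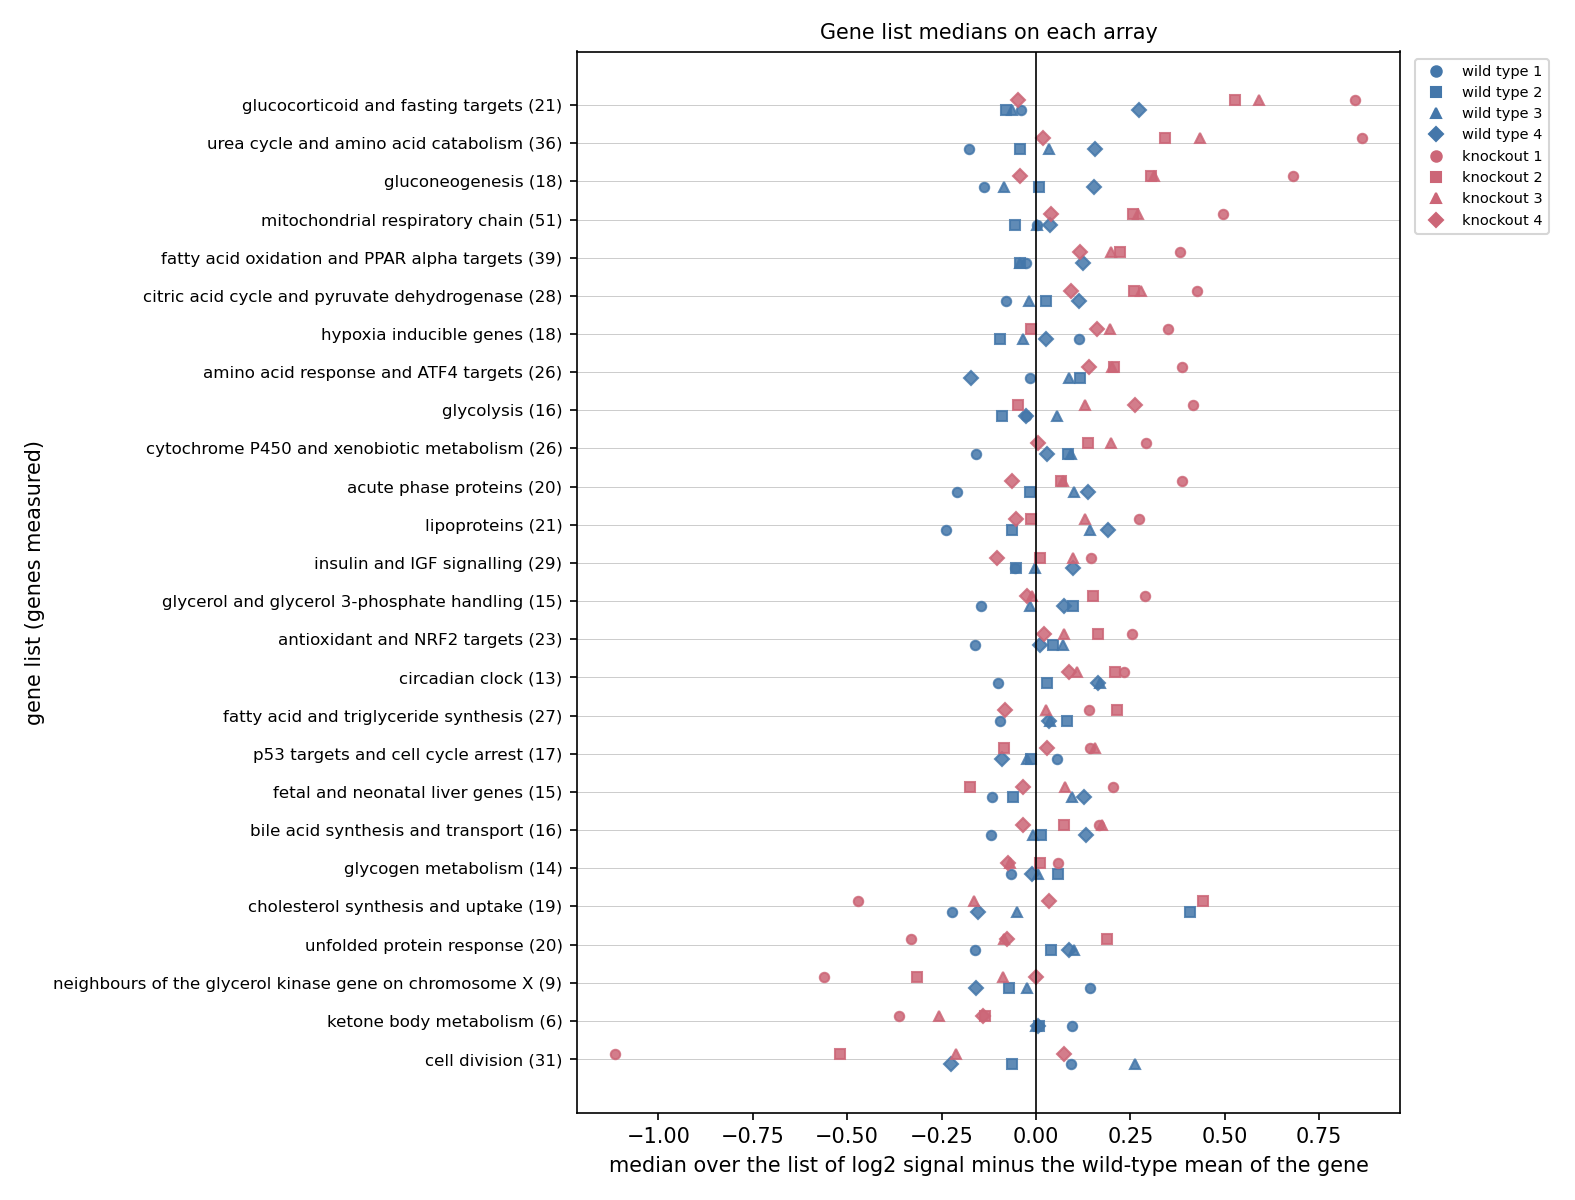
For each of the 26 gene lists (number of genes measured in parentheses), the median over the list of a gene's log2 signal minus its wild-type mean, 1 point per array. Knockout 1 stands farthest out for cell division (-1.12) and amino acid catabolism (0.86), where knockout 4 lies among the wild-type arrays (0.07 and 0.02).

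The remaining 14 gene lists were not called. In glycolysis 1 of 16 measured genes rose, the phosphoglycerate mutase Pgam1 (1.08 ± 0.17; limma adjusted p = 0.0441), beside Tpi1 at 0.51 ± 0.12 (median 0.16; 4 rose and 1 fell adjusted over the list alone). No member of the other 12 lists besides glycerol handling passed over all genes. In insulin and IGF signalling, Igfals, which carries IGF in serum, stood at -1.20 ± 0.21 and Irs2 at 0.71 ± 0.17 (median 0.09, mean -0.01; 2 rose and 3 fell adjusted over the list alone). Glycogen metabolism (median -0.03, called in neither direction although camera leaned higher) had Pgm1 at 0.61 and Gaa at 0.60, with 2 rises and 2 falls adjusted over the list alone. Among p53 targets (median 0.03; 2 and 2) Gadd45a stood at -0.61 and Trp53inp1 at 1.56, and among fetal and neonatal liver genes (median 0.02, mean -0.03; 1 and 0) the brighter Peg3 probe set at 0.83 and Cdkn1c at -0.85. In bile acid synthesis (median -0.000261, mean 0.12; 1 and 0), Cyp27a1 stood at 1.48 ± 0.36.

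Ketone body genes had a median of -0.23 with 5 of 6 below 0, Slc16a1 at -0.57 and Bdh1 at -0.29. Fatty acid and triglyceride synthesis had a median of 0.05, with Acsl4 at 0.70 and Elovl5 at -0.69, and cholesterol synthesis one of -0.09, where camera leaned higher, with Ebp at 0.46 and Tm7sf2 at 0.28. Lipoprotein genes had a median of 0.09 and were called in opposite directions in the sets, higher in the first (0.29) and lower in the second (-0.13), with Mttp at 0.53 and Apom at 0.31, and Slc27a5 of the bile acid list stood at 0.54. The unfolded protein response had a median of -0.11, with Edem1 at 0.54 and Herpud1 at 0.78, and the circadian clock one of 0.08, with Per1 at 1.14 and Arntl at 0.51. The chromosome X neighbours of Gk had a median of -0.20, with 7 of 9 below 0, Eif2s3x at -0.48 and Pola1 at -0.55; camera called this list lower in the first set (-0.49; adjusted p = 0.0169) and not in the second (0.00; adjusted p = 0.645). In these 7 lists 0 members passed adjusted over the list alone. Camera's adjusted p for the 14 lists ran from 0.0650 for glycolysis to 0.888, and from 0.369 with an estimated correlation.

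Of 13 lists of cell type markers tested, camera called 0 with the preset correlation and 0 with an estimated one, and fry called 0. At an unadjusted p under 0.05 there were 3 lists with the preset correlation, 0 with an estimated one and 0 by fry. These were B lymphoid markers (median -0.49, 0 of 8 above 0), hepatocyte markers (0.10, 11 of 11 above 0) and T and natural killer markers (-0.24, 1 of 5 above 0, where 0 rose and 2 fell adjusted over the list alone). Their adjusted p by camera was 0.106 for B lymphoid and 0.137 for the other markers, and adjusted p = 0.845 with an estimated correlation. Gzma stood at -1.15, Gzmb at -0.69, Blnk at -0.50, Ms4a1 at -0.49, Hnf4a at 0.73 and Apob at 0.30. Median log2 fold changes were -0.14 for erythroid cells (Car1 at 0.94, Rhd at -0.66), -0.23 for granulocytes (Chil3 at 0.94, Camp at -0.39) and -0.20 for megakaryocytes (Gp9 at -1.05, Ppbp at -0.30). They were 0.06 for macrophages (Vsig4 at 0.54, Cd68 at -0.34), -0.08 for sinusoidal endothelium (Kdr at -0.50, Emcn at 0.40) and -0.11 for stellate cells (Col3a1 at -1.03, Lum at -0.52). For tissues that a dissected liver could carry, medians were 0.29 for pancreas (Cela1 at 0.34, Rnase1 at 0.73), 0.17 for fat (mean -0.02; Retn at -0.46, Lipe at 0.22), -0.22 for intestine (Fabp2 at -1.39, Lgals4 at 0.30; 1 fell adjusted over the list alone) and -0.07 for bile duct (Cldn7 at -0.07, Epcam at -0.13). Too few skeletal muscle markers were measured for a test, and Mylpf stood at 0.40. In the first set camera called hepatocyte markers higher (0.32) and erythroid markers lower (-0.51), and in the second erythroid markers were called higher (0.17), beside 5 other lists called lower.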

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

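The tests of the sex signal, the one with the pyruvate carboxylase ratio and the splits with the hybridisation set as a block were chosen only after the result was seen. Of 282 groups of 4 arrays, 14 held a value far from the other 3, where chance gives 14.1, or about 1 in 20. There were 5 on wild type 4, 4 on knockout 1, 3 on wild type 1, 1 on wild type 3 and 1 on knockout 3.

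On the array labelled wild type 4, Xist stood at 10506.3 against 196 to 396 on the other wild-type arrays, 26.5 times the highest other array. A mixture of male and female RNA is argued against, since the 5 Y-linked probe sets lay at a median ratio of 0.129 to the mean of the other 7 arrays, the highest at 0.177. A sixth Y-linked probe set, for Orly, whose probes are shared between transcripts, had a signal of 293.5 there against a mean of 268 and was left out of that test after its value was seen. A swap between the groups is argued against as well, since on the 2 probe sets with the smallest p when this array is left out, it stood at least 10.3 times above the highest knockout array. A female liver in place of a male one may account for the signal, with the highest Y-linked ratio of 0.177, and which liver it was stays open.

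The number of probe sets called could be read as an effect of RNA quality or of how the 8 arrays happen to divide. Of the 35 splits of the arrays into 4 and 4, 2 gave at least the 61 probe sets of the real split, so chance is not excluded by this count. The highest other, 311, is the split that follows the hybridisation set and points to a structure of the samples, and the other 33 gave 0. With that set as a block, 103 probe sets were higher and 81 lower, and of the 18 splits balanced over the set only 1, the real one, gave as many as these 184, the highest other giving 0; 18 splits are too few for a share under 0.05. The called probe sets kept 0.965 of their median log2 fold change with the actin ratio as a covariate and 0.976 with the pyruvate carboxylase ratio. The groups overlapped in each ratio. Probe sets are called for a small spread within the groups, and one that followed these overlapping ratios would seldom be called. A high share was thus likely either way, and it does not decide whether RNA quality plays a part. How far a biological difference between the genotypes accounts for the number of calls stays open, as does a part played by RNA quality in the calls and the gene lists. The 2 unnamed probe sets with the smallest p were also called in the second hybridisation set alone, at log2 fold changes of -3.45 and -3.77.

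Other values far from the rest of their group are given with the range of the other 3 arrays. The signal of Acot2 on wild type 4 was 1180.8 (851.7 to 896.0), that of Rhd on wild type 4 was 4637.3 (6798.8 to 7213.3), and that of Cth on wild type 3 was 5636.8 (10066.6 to 10283.5). Cldn7 on wild type 1 stood at 107.5 (222.0 to 231.9), Tm7sf2 on knockout 1 at 2622.4 (2319.5 to 2363.3), Atp5c1 on knockout 1 at 18192.2 (13471.6 to 13997.5) and Idh3a on knockout 3 at 4882.1 (3882.4 to 4042.2). The actin 3'/5' ratio was 1.74 on knockout 1 (1.21 to 1.27) and 1.32 on wild type 1 (1.24 to 1.25). The list median was 0.12 for fatty acid oxidation on wild type 4 (-0.04 to -0.03), 0.27 for glucocorticoid targets on wild type 4 (-0.08 to -0.04) and 0.0949 for ketone body genes on wild type 1 (-0.00115 to 0.01). That of sinusoidal endothelial markers was 0.15 on knockout 1 (-0.12 to -0.09).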

How the results depend on the processing

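The settings with the hybridisation set were chosen only after the result was seen. Against 30 probe sets higher and 31 lower, there were 8 and 13 with no filter, 8 and 14 at a signal of at least 100, 63 and 48 at 400, 4 and 14 with no intensity trend, and 382 and 367 with array weights. With the hybridisation set as a block there were 103 and 81, without wild type 4 as well 103 and 51, in the first set 24 and 6, and in the second 0 and 2. At an adjusted p under 0.01 there were 0 and 2 and under 0.10 there were 166 and 138. The cause of these shifts was not tested, except that the sets and the settings without 1 array hold fewer samples. Without 1 array the counts ran from 0 to 211 higher and from 2 to 123 lower: 22 and 43 without wild type 1, 4 and 2 without wild type 4, 7 and 15 without knockout 1, 211 and 123 without knockout 4, and 0 and 2 without wild type 2, wild type 3, knockout 2 or knockout 3. All 61 probe sets, where tested, kept their sign in every setting run. Their groups do not overlap, so settings that leave out arrays could not change a sign. The replicate number as a block gave 26 and 30, 31 of them shared; deviations of arrays with the same number correlated at 0.22, 0.40, 0.34 and 0.05, and only replicates 1 and 2 correlated best with their own number. All pairs across the groups within a hybridisation set ran from 0.05 to 0.40, and between the sets from -0.34 to -0.04. Deviations sum to 0 over the arrays of a group, so positive values within the sets bring negative ones between them. The numbers were not taken as pairs, since 1 correlation was under 0.1; whether they pair the livers stays open.

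Camera called 12 gene lists and 0 cell type lists. It called 0 gene lists with an estimated correlation, fry called 0, and in the second hybridisation set camera called 6. Camera called 8 at a signal of at least 400, 9 with quantile normalization, with the replicate block and without wild type 1 or knockout 1, 10 with array weights, 11 with the mean of a gene's probe sets and without knockout 3, and 12 to 14 in the other settings. With a 3'/5' ratio as a covariate there were 157 probe sets higher and 91 lower and 12 lists for Gapdh, 58 and 45 and 10 lists for actin, and 38 and 34 and 9 lists for pyruvate carboxylase. Cell type lists called were 1 with the replicate block, 2 in the first set, 6 in the second and 0 to 3 without 1 array. In the second set the median of the called acute phase list turned to -0.12, and camera called lipoproteins (-0.13) and erythroid markers (0.17) against the sign over all arrays and against its calls in the first set (0.29 and -0.51); the cause was not tested. Named genes past the threshold stayed past it in 349 of 648 values and reversed in 0. As their groups do not overlap, leaving out arrays could not reverse them. The glycerol kinase result has no value under any setting. Changes of 1.5-fold were recovered for 23.5% of simulated probe sets, in data that gave 376 calls. The real data gave 61 calls and so a stricter cutoff, under which fewer such changes would be recovered. The smallest absolute log2 fold change called was 0.72, so smaller changes are mostly missed at this number of arrays.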

Other observations

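The lists of interferon-gamma inducible and purine synthesis genes were chosen only after the result was seen, from called genes that were then left out of their tests. Interferon-gamma inducible genes, which serve antigen presentation and defence inside cells, lay mostly below 0 in the knockout: 20 of 22 measured, with a median log2 fold change of -0.58. Gbp6 stood at -1.92, Psmb9 at -1.40 and Gbp2 at -1.01, and 0 passed over all genes tested. Lower expression of these genes as a group may be a part of the knockout's difference, but camera gave p = 6.70e-09 with the preset correlation and p = 0.0657 with an estimated correlation, so the test leaves it open. Lymphoid markers lay below 0 with them, at a median of -0.49 for B lymphoid cells (0 of 8 above 0) and -0.24 for T and natural killer cells, with Gzma at -1.15, while macrophage and Kupffer cell markers had a median of 0.06 with 7 of 13 above 0. The groups overlapped for B lymphoid markers, whose medians ran from -0.57 to 0.60 on the wild-type arrays and from -0.98 to 0.12 on the knockout arrays. The interferon-gamma list holds genes that B cells also express, Cd74 (-0.78), H2-Aa (-0.85), H2-Ab1 (-0.37) and H2-Eb1 (-0.57), and a smaller share of immune cells was not tested as an explanation.

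Purine synthesis genes were tested because Ampd2 (0.91) and Ppat (1.08), both of purine metabolism, rose. The other 11 measured had a median of -0.23 with 3 above 0 and the highest, Paics, at 0.58 (camera p = 0.351 with an estimated correlation), which argues against a rise of the group.

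DNA of another strain carried along with the targeted allele could change genes near it. With each gene read from its brightest probe set alone, so that fewer genes count as called than in the comparison above, 0 of 16 genes within 10 Mb were called by limma and 3 had an unadjusted p under 0.05, against 30 of 10832 called elsewhere (0.277%; Fisher's exact p = 1, two-sided). The upper 95% bound of the share nearby, 20.6%, is too wide to decide. The list of neighbours fixed before the data were examined was called lower by camera in the first hybridisation set alone, with medians of -0.49 there and 0.00 in the second.

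Of the 35 splits of the arrays, 12 gave at least the 12 gene lists of the real split with the preset correlation, and the highest other gave 16, so chance is not excluded for the number of lists called.

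Gins2 had a log2 fold change of -3.0 in the first hybridisation set and 0.01 in the second, and Pvr 2.32 and -1.30 (limma adjusted p of the difference = 0.0410 for each). A probe set without a gene name here rose by 2.26 (limma adjusted p = 0.0197).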
